A study of Sus scrofa with 4 samples.

How the data were processed

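Small RNA sequencing was done on 4 libraries of primary pig cells, with 1 library in each group. The cells were vascular stem cells at passage 1. They came from the longissimus dorsi muscle of the back (IVSC, intramuscular) or from subcutaneous fat (SVSC). Each culture was sequenced undifferentiated and after MDI, an adipogenic medium with 0.5 mM IBMX (a phosphodiesterase inhibitor), 0.25 µM dexamethasone (a glucocorticoid) and 5 mg/l insulin. IBMX and dexamethasone were withdrawn after 3 days and the growth medium returned at day 6. Differentiation then went on for 3 or 4 days, and which of these applies to IVSC MDI and to SVSC MDI is not given, so their harvest days may differ. All media held 20% serum. Libraries were made from about 10 µg of total RNA, from fragments of 16 to 35 nt, with 12 cycles of PCR, and were read for 36 cycles on an Illumina 1G Genome Analyzer. Whether the cultures came from the same animal is not given in the sources used here.

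The deposited values are counts: per the file headers, each file lists read counts per feature from 4 resources, namely Sus scrofa hairpins, Ensembl non-coding RNAs of Sscrofa9.61, piRNAs and Rfam. A file gives for each feature the reads that match the mature miRNA exactly, all reads on the mature miRNA, on the star strand and on the rest of the hairpin, and their total. In the file of the SVSC library, a few Rfam tRNA entries hold blank or damaged values in the deposited column of uniquely matching mature reads. The hairpin entries of that column are whole read counts and only these were used. In the same file 3 features have no resource name and were left out. One unnamed entry of the SVSC MDI file holds 4071523, the sum of that file's expression values, and was left out too. The aligner, the mismatches allowed and the adapter trimming tool are not given in the sources used here. The submitters' processing notes name the mouse build mm9 without saying what it was used for. No coordinates are reported.

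The measure used was the total number of reads on the hairpin of a miRNA. Copies of a hairpin share most of their reads, so a miRNA's reads were counted once over its copies (the largest copy plus the uniquely matching reads of the others). Exceptions with many mature reads unique to a copy were miR-365 (106% of the mature reads of the larger copy, summed over copies), miR-128 (30.7%), miR-181b (15.3%), miR-92a (12.1%) and miR-101 (11.6%). The plan had been to sum the copies, and that sum was run as an alternative. Names of miR-18 and miR-20 were updated to miR-18a and miR-20a through the synonyms of a pig gene table. In all, 189 miRNAs had a read. Of these, 57 had most of their reads on the rest of the hairpin and 5 on the star strand, miR-143 among the first, so the arm a read came from was not used. The piRNA and Rfam entries were not used in the comparisons.

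Counts were scaled to CPM over the miRNA reads of a library. For each pair of libraries the ratio was given with an exact 95% interval (Clopper-Pearson, conditional on the reads of both libraries, SciPy 1.17.1 in Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6). A count of 0 was set to a floor of 3 reads. miRNAs at 10 CPM or more in at least 1 of the 2 libraries were compared, and one was called higher or lower when its ratio was at least 2-fold and its interval excluded 1. Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. With 1 library per group there is no check between replicates and no p-value for a pair of libraries. These ratios compare libraries, and any difference between animals or preparations is part of them. On data simulated by drawing both libraries of a pair from 1 profile (189 miRNAs, 50 draws), the interval held a ratio of 1 in 95.6%, 96.4%, 95.5% and 95.7% of cases for the 4 comparisons.

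The 4 libraries held 13252168 (IVSC), 14810112 (IVSC MDI), 17937121 (SVSC) and 2573249 (SVSC MDI) miRNA reads. A count of 3 reads, the limit that a count of 0 allows, corresponds to 0.226, 0.203, 0.167 and 1.17 CPM. The SVSC MDI library is thus the least precise.

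Effects shared by both cultures were fitted on all 4 libraries with edgeR 4.0.16 (R 4.3.3, limma 3.58.1), using filterByExpr, TMM scaling and quasi-likelihood F tests. The additive model held culture and MDI state, with the other factor as a block, and left 1 residual degree of freedom. The fitted prior degrees of freedom were infinite, so the spread of each miRNA was taken from all miRNAs together. A difference of the MDI effect between cultures adds to this shared spread, and hardly to that of its own miRNA. The p-values do not measure spread between animals or preparations. p-values were adjusted by Benjamini-Hochberg at 0.05 over 179 miRNAs. The SE given with a log2 ratio was worked back from the test, as the absolute log2 ratio divided by the square root of F. DESeq2 1.42.0 was run as the other tool. On simulated counts (179 miRNAs, 40 of them changed, 20 draws, dispersion 0.05), the edgeR fit found 26.4% of 2-fold, 94.5% of 4-fold and 98.8% of 8-fold changes, with 4.5%, 3.1% and 3.3% false calls. These counts are quieter than the data, where the fitted dispersion was 0.196. At that dispersion the fit found 0.9%, 26% and 73.9% of the changes, with 3 of 10, 10 of 218 and 21 of 612 calls false.

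Before the data were examined, the comparisons, the alternatives except those named as added, 23 lists of miRNAs and a rule for naming miRNAs were fixed. The rule names, per comparison, the 10 largest changes in each direction among miRNAs at 100 CPM or more, the 10 most abundant miRNAs of each library, list members, miRNAs at that level that changed 2-fold in opposite directions in the 2 cultures, and the 10 smallest p-values of each fit. The lists hold miRNAs reported to promote or to inhibit adipogenesis, and miRNAs linked to brown fat. Further lists are families and clusters: let-7, miR-30, miR-29, miR-17-92 with its paralogs, miR-15 with miR-16, the X-linked miR-424 and miR-503 cluster, miR-34, miR-23 with miR-27 and miR-24, miR-221 with miR-222, miR-99 with miR-125, miR-181, the HOX clusters, the DLK1-DIO3 locus and the CREB-responsive miR-132 and miR-212. The rest are markers of skeletal muscle, endothelium, perivascular mesenchyme, blood, epithelium, and liver or neurons. A member counts as detected at 10 CPM in at least 1 library. Lists with at least 3 detected members were given a median log2 ratio and its percentile among 10000 random lists of the same size and matched abundance. Some miRNAs are in more than 1 list. For example, miR-133a and miR-133b are in the lists of both brown fat and skeletal muscle.

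The alternatives tried were scaling by TMM, by DESeq2 size factors, to all reads of the file, and without the most abundant miRNA over the 4 libraries, miR-21; no filter and a filter of 100 CPM; thresholds of 1.5-fold and 4-fold; a pseudocount of 1; and only exactly matching reads. For the fits they were DESeq2 size factors, the DESeq2 test, no filter, no block, and each library left out in turn. Mature reads alone, hairpin copies summed, and libraries thinned to the depth of the SVSC MDI library were added after seeing the data. Exact and mature reads were scaled to the library's own total of such reads, which by itself moves every log2 ratio of a comparison by 1 factor. In IVSC, IVSC MDI, SVSC and SVSC MDI, mature reads were 61.4%, 58.6%, 71.2% and 57.5% of the miRNA reads. Exact reads were 30.8%, 29.0%, 27.3% and 35.8%. The total of all reads counts some reads more than once. With hairpin copies and 1 pair of Ensembl transcripts taken once, it would move the log2 ratios by 0.13 in place of 0.22 for MDI in IVSC, -0.28 in place of -0.49 for MDI in SVSC, 0.11 in place of 0.18 between undifferentiated cultures and -0.29 in place of -0.52 after MDI. Figures were drawn with matplotlib 3.10.9.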

Results

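The miRNAs of pig vascular stem cells from muscle (IVSC) and from subcutaneous fat (SVSC) were counted before and after adipogenic induction with MDI. The 4 groups were IVSC, IVSC MDI, SVSC and SVSC MDI, each with 1 library (n = 1), and the series set out to compare the miRNAs of adipogenesis in both cell types. The libraries held 13252168, 14810112, 17937121 and 2573249 miRNA reads in that order, over 187, 186, 182 and 181 miRNAs. Abundance is given as CPM, reads scaled to the library's miRNA reads, and ranges in parentheses are exact 95% counting intervals of the ratio before them. Rose and fell stand for a change of at least 2-fold whose interval excludes 1. Unless another scaling is named, calls are those under scaling to miRNA reads. miRNAs that pass 2-fold only under another scaling are counted there but mostly not named.

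A pair of miRNAs made up most of each library. miR-143, a miRNA of smooth muscle and other mesenchymal cells that promotes adipocyte differentiation, took 35.0% of the miRNA reads in IVSC, 38.8% in IVSC MDI, 25.6% in SVSC and 39.0% in SVSC MDI. miR-21, abundant in many proliferating cells, took 29.6%, 33.6%, 44.1% and 26.3%. miR-378, encoded within the gene of the metabolic coactivator PGC-1β, took 13.1%, 6.42%, 6.55% and 8.86%. miR-148a took 4.45%, 3.04%, 1.65% and 4.30%. let-7f took 3.05%, 3.54%, 4.79% and 3.82%, and let-7a took 1.62%, 1.50%, 4.58% and 2.09%. The 10 most abundant miRNAs together took 89.5%, 89.9%, 90.4% and 88.8%. The rest of the 10 were miR-23a, miR-152, miR-30e and miR-27a in IVSC, and miR-23a, miR-30e, miR-30a and miR-10b in IVSC MDI. In SVSC they were miR-30d, miR-30e, miR-100 and miR-103, and in SVSC MDI miR-10b, miR-27a, miR-23a and miR-145. The exact binomial 95% intervals of these shares were at most 0.12 percentage points wide and cover counting error only. Rfam entries of the mir-143 family held 1876707, 1506083, 1756280 and 268119 reads in IVSC, IVSC MDI, SVSC and SVSC MDI, which these shares leave out. Of the miR-143 reads counted here, 99.95% lay on the rest of the hairpin. As deposited, hairpins held 70.2%, 77.0% and 75.4% of all reads in IVSC, IVSC MDI and SVSC, against 55.01% in SVSC MDI, where Ensembl non-coding RNAs held 38.5% (19.3%, 13.99% and 15.7% in the others). These sums count some reads more than once. With hairpin copies and a pair of Ensembl transcripts of near equal counts taken once, hairpins held 73.2%, 79.8%, 78.8% and 65.1%, and Ensembl non-coding RNAs 14.3%, 10.2%, 11.01% and 26.4%.

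In IVSC, the question was which miRNAs changed with adipogenic induction. miR-206, a miRNA specific to skeletal muscle and its precursor cells, fell 34.9-fold with MDI (33.4 to 36.5), from 64588 to 2068 reads. miR-146b, which promotes adipocyte differentiation, rose 7.83-fold (7.37 to 8.33), and miR-145, a miRNA of contractile smooth muscle, rose 5.30-fold (5.21 to 5.40). miR-221, which represses inhibitors of the cell cycle, fell 4.47-fold (4.37 to 4.57), and miR-503, which targets cell cycle genes, fell 5.14-fold (4.71 to 5.61). Of 152 miRNAs, 25 rose and 36 fell, 4 and 7 of them by at least 4-fold. The other large rises were those of miR-193a (3.81-fold; 3.53 to 4.12), miR-30b (3.72-fold; 3.61 to 3.83), miR-34a (3.42-fold; 3.26 to 3.60), miR-425 (3.22-fold), miR-186 (2.63-fold), miR-23b (2.62-fold), miR-34c (2.56-fold) and miR-181a (2.56-fold). The other large falls were those of miR-7 (6.71-fold; 6.30 to 7.14), miR-411 (4.89-fold), miR-381 (4.59-fold), miR-148b (3.90-fold; 3.83 to 3.98), miR-127 (3.79-fold), miR-744 (3.70-fold) and miR-299 (3.56-fold). On the reads of the mature miRNA alone, miR-221, miR-381 and miR-299 had log2 ratios of -0.48, 0.26 and -0.07, that of miR-381 on only 11 and 14 reads. Of the 61 calls 45 were made on mature reads as well, and among list members those of miR-542 (572 and 611 reads), miR-136, miR-20a, miR-378, miR-92b, miR-122, miR-376a, miR-376b and miR-376c were not. Over the 4 libraries miR-20a and miR-378 had 98.9% and 99.7% of their reads on the mature miRNA. Their calls were lost mostly through the change of total.

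Of the miR-30 family, which promotes adipogenesis, 3 of 5 members rose in IVSC and none fell. They were miR-30a (2.38-fold), miR-30b and miR-30c (2.41-fold). The log2 ratios of the family ran from 0.12 to 1.90, and their median lay at percentile 99.4 of random lists and was positive under all 5 scalings. Of 11 detected miRNAs of the imprinted DLK1-DIO3 locus, 8 fell, miR-411, miR-381, miR-127 and miR-299 by the most. miR-376a rose 2.81-fold (2.07 to 3.89), and the locus had a median of -1.22 (percentile 0.46), negative under all 5 scalings. Of the proliferation-linked miR-17-92 clusters, 4 of 9 members fell and none rose (median -0.999, percentile 5.84), with miR-363 the furthest at 3.56-fold (3.03 to 4.18). Under scaling to all reads only 1 was called and the median stayed negative. Of the miR-15 and miR-16 family, 3 of 7 fell (median -0.79, percentile 12.7), namely miR-503, miR-15b and miR-195. Under scaling to all reads miR-503 alone did. Of the X-linked cluster 2 of 6 fell, miR-503 and miR-542 (median -0.32, percentile 17.9). Both p53-responsive miRNAs, miR-34a and miR-34c, rose.

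Of 19 detected miRNAs reported to promote adipogenesis, 5 rose in IVSC and 3 fell, and the median of 0.03 turned to -0.01 under TMM. Those that rose were miR-146b, the hypoxia-induced miR-210 (4.84-fold; 4.16 to 5.65), miR-30a, miR-30b and miR-30c. Those that fell were miR-378 (2.04-fold), miR-20a (2.04-fold) and miR-320 (2.26-fold), all short of 2-fold under scaling to all reads. Among miRNAs reported to inhibit it, 2 of 17 rose (miR-145 and miR-224) and 3 fell (miR-221, miR-130a and miR-130b, the latter pair repressors of PPARγ), with a median of 0.07 that stayed positive under all 5 scalings. Of the brown fat list, miR-193a and miR-455 (2.01-fold) rose and miR-133b fell, of 5 (median 0.53), miR-455 staying short of 2-fold under TMM and DESeq2 scaling. No member of the let-7 (7 members, median 0.21), miR-29 (3 members, median 0.52) or HOX (3 members, median 0.14) lists passed 2-fold. Under scaling to all reads miR-10b of the HOX list did. In the miR-23, miR-27 and miR-24 and miR-99 and miR-125 lists only miR-23b and miR-125a (2.41-fold) rose, of 5 members each (medians 0.24 and 0.71). miR-181a rose and miR-181c fell 2.64-fold, of 4 family members (median 0.26), and of the pair miR-221 and miR-222 the former fell. The list of miR-132 and miR-212 had no member in the files.

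Of 5 detected skeletal muscle miRNAs in IVSC, miR-206 and miR-133b (4.18-fold; 3.62 to 4.83) fell, while miR-1 had a ratio of 0.710 (0.694 to 0.727), miR-133a 1.09 and miR-499 1.04 (median -0.49). Of the perivascular and mesenchymal list, miR-145 rose and miR-214 fell (2.11-fold), of 5 (median 0.09). The endothelial miR-126 had a ratio of 0.668 and the blood cell miRNA miR-142 one of 0.911. The neuronal miR-9 rose 2.19-fold, from 168 to 411 reads, and the liver miRNA miR-122 fell 3.38-fold, from 139 to 46 reads. The epithelial list was not detected in any library (at most 9 reads of miR-205). Scaling to all reads moved every log2 ratio by 0.22 and gave 32 rises and 21 falls, and among list members it left miR-130a, miR-214, miR-376b and miR-376c short of 2-fold as well. miR-181c (2.27-fold), miR-376a (3.28-fold) and miR-122 (2.90-fold) kept their direction and were not called only because they lay below 10 CPM of all reads. The total of all reads counts some reads more than once. With these taken once it would move the log2 ratios by 0.13. At that move miR-320, miR-15b, miR-106a, miR-376b and miR-376c would stay past 2-fold lower. Under all 5 scalings, 22 of the rises and 21 of the falls were called, all 20 named first among them.

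**Figure D1:**
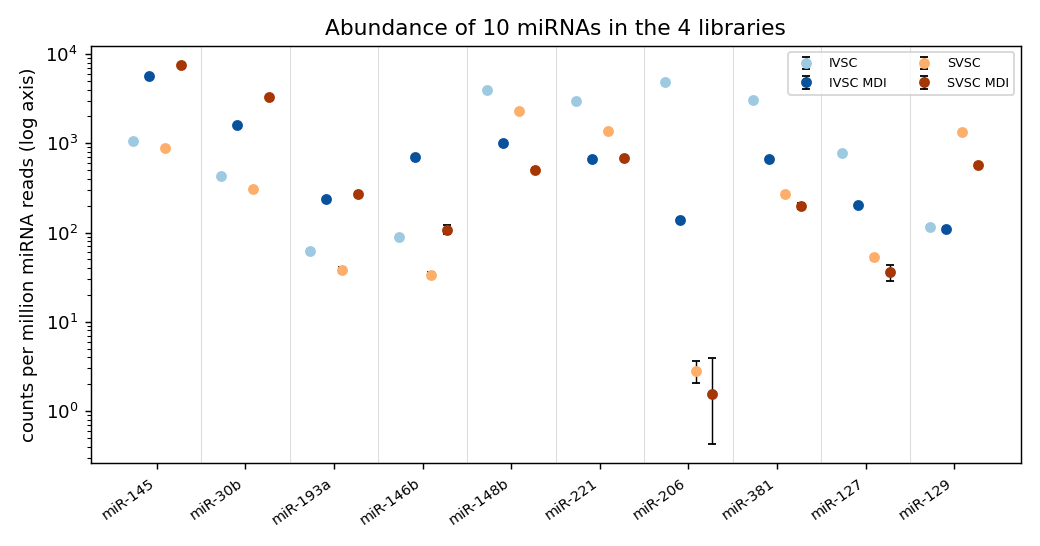
CPM (log axis) of 10 miRNAs in the 4 libraries, 1 point per library; bars are exact 95% counting intervals, mostly smaller than the points. miR-145, miR-30b, miR-193a and miR-146b were higher with MDI in both cultures under all 5 scalings, miR-148b was lower, and miR-206, miR-381 and miR-127 were higher in IVSC than in SVSC.

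In SVSC, the same question was asked. The adipogenic miR-30b rose 10.97-fold with MDI (10.6 to 11.3), and miR-10b, encoded in a HOX gene cluster, rose 10.0-fold (9.87 to 10.2) to 15493 CPM. miR-339 rose 15.1-fold (13.98 to 16.4), and the smooth muscle miRNA miR-145 rose 8.31-fold (8.14 to 8.49). miR-148b fell 4.57-fold (4.33 to 4.83), miR-20a, of a cluster that promotes proliferation, 4.24-fold (3.97 to 4.53), and miR-100 4.19-fold (4.07 to 4.31). Of 146 miRNAs, 50 rose and 32 fell, 23 and 9 of them by at least 4-fold. The other large rises were those of miR-128 (9.47-fold; 8.33 to 10.8), miR-133a (9.18-fold; 8.03 to 10.5), miR-505 (8.25-fold), miR-193a (7.04-fold; 6.33 to 7.84), miR-30c (5.57-fold) and miR-30a (5.20-fold). The other large falls were those of miR-130b (3.75-fold; 3.43 to 4.11), miR-320 (3.47-fold), miR-4331 (3.23-fold), miR-103 (3.09-fold; 3.01 to 3.18), miR-140 (3.07-fold), miR-1 (2.75-fold) and miR-744 (2.67-fold). On the reads of the mature miRNA alone, miR-140 had a log2 ratio of 0.28 and miR-133a had 19 reads before and 0 after MDI, and on exactly matching reads miR-20a had a log2 ratio of 0.46. Of the 82 calls 62 were made on mature reads as well, and those of miR-4331 and of the list members miR-542 (625 and 65 reads), let-7a, miR-130a, miR-450b, miR-122, miR-142 and miR-494 were not. Scaling to the total of mature reads raises every log2 ratio here, that of miR-140 included. Over the 4 libraries let-7a, miR-130a and miR-450b had 99.1%, 98.8% and 95.5% of their reads on the mature miRNA. Their calls were lost mostly through this change of total.

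Of the miR-30 family in SVSC, miR-30a, miR-30b and miR-30c rose and miR-30d fell (2.39-fold; 2.34 to 2.44), with a median of 2.38 (percentile 99.8) that was positive under all 5 scalings. Of 5 brown fat miRNAs, 4 rose: miR-193a, miR-133a, miR-133b (12.2-fold; 7.22 to 21.1) and miR-455 (3.11-fold; 2.81 to 3.43). Their median of 2.82 lay at percentile 99.5 and was positive under all 5 scalings, though miR-133a and miR-133b are also muscle miRNAs. miR-133b rests on 24 and 42 reads, and miR-133a had 19 and 0 reads on the mature miRNA. The list holds miRNAs linked to brown fat, whichever way they act. Among miRNAs reported to promote adipogenesis, 7 of 19 rose, with miR-148a (2.60-fold), miR-146b (3.23-fold) and miR-92a (3.20-fold) beside the miR-30 members and miR-210 (3.40-fold). In the same list 6 fell (miR-103, miR-107, miR-30d, miR-320, miR-17 and miR-20a), and the median of 0.32 was negative under the other 4 scalings. In the list of those reported to inhibit it, miR-145 and let-7e (2.63-fold) rose and let-7a (2.19-fold), miR-130a and miR-130b fell, of 17, and the median of 0.35 was negative under the other 4 scalings. miR-148a and let-7e were short of 2-fold under those 4.

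The miR-17-92 clusters split in SVSC: miR-92a, miR-19a and miR-19b rose and miR-363 (9.81-fold; 6.45 to 15.7), miR-20a, miR-106a (4.02-fold) and miR-17 fell, of 9 members. Their median of -0.46 was negative under all 5 scalings, with miR-92a the only rise left under the other 4. Of the miR-99 and miR-125 list, miR-125a (4.85-fold; 4.54 to 5.18), miR-99a (3.98-fold) and miR-125b (2.33-fold) rose and miR-100 fell, of 5 (median 1.22), miR-125b being short of 2-fold under the other 4 scalings. Of the miR-23, miR-27 and miR-24 list, miR-23a (2.44-fold) and miR-23b (2.79-fold) rose, of 5 (median 0.75), miR-23a being short of 2-fold under the other 4 scalings and miR-23b under TMM and all reads. let-7e and let-7a were the only members of 7 past 2-fold in the let-7 family, whose median of 0.12 was negative under the other 4 scalings. miR-34a rose 4.51-fold (4.28 to 4.76). miR-34c had a ratio of 0.533 and was past 2-fold lower under the other 4 scalings. Of 3 HOX cluster miRNAs, miR-10b rose and miR-196b fell 5.46-fold (3.98 to 7.71; median -0.04). Of the X-linked cluster, miR-542 (2.46-fold) and miR-450b (2.15-fold) fell, of 6 (median -0.18). No member of 7 in the miR-15 and miR-16 family passed 2-fold at first, and its median of 0.44 was negative under TMM and under scaling to all reads. miR-15a (log2 ratio -0.95) and miR-503 (-0.85) were past 2-fold lower under the other 4 scalings. miR-221 and miR-222 had ratios of 0.505 and 1.28, and miR-221 was past 2-fold lower under the other 4 scalings as well. Medians of the miR-29 (0.11; miR-29c rose, of 3), miR-181 (0.23; miR-181d fell, of 4) and DLK1-DIO3 lists (0.30; miR-494 rose, of 11) were negative under the other 4 scalings. The call of miR-29c was lost under these 4 and that of miR-494 under TMM and all reads.

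Of the skeletal muscle list in SVSC, miR-133a and miR-133b rose and miR-1 fell, of 5, and the median of 0.19 was negative under the other 4 scalings. miR-206 stood at 50 and 4 reads. miR-145, miR-199a (2.16-fold) and miR-199b (2.15-fold) rose among 5 perivascular miRNAs (median 1.11), of which miR-145 alone was called under the other 4 scalings. The blood cell miRNA miR-142 rose 3.59-fold, from 97 to 50 reads in the shallower library (2.50 to 5.11), the endothelial miR-126 had a ratio of 1.21, miR-9 rose 3.49-fold, and miR-122 fell 12.4-fold, from 432 to 5 reads. The scaling set the balance of rises and falls in SVSC. Every log2 ratio moved by -0.50 with TMM (36 rises and 45 falls), -0.43 with DESeq2 size factors (38 and 42), -0.49 with all reads (33 and 44) and -0.40 without miR-21, the most abundant miRNA over the 4 libraries (40 and 41). With all reads miR-133b (8.71-fold) and miR-142 (2.57-fold) stayed higher and were not called only because they lay below 10 CPM of all reads. Under all 5 scalings, 33 rises and 31 falls were called, all 20 named first among them.

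The MDI responses of the 2 cultures were then set side by side. Across 155 miRNAs, the log2 ratios of IVSC and SVSC had a Pearson r of 0.581 and a Spearman rho of 0.568, and 70.3% had the same sign. miRNAs are not independent replicates, so no p-value is given, and the 2 ratios share no library. In both cultures 22 miRNAs were at least 2-fold higher with MDI, among them miR-145, miR-30b, miR-193a, miR-146b and miR-34a, and 15 were at least 2-fold lower, among them miR-148b, miR-130b and miR-20a. Under scaling to miRNA reads, no miRNA at 100 CPM or more changed 2-fold in opposite directions. miR-34c, with log2 ratios of 1.36 in IVSC and -0.91 in SVSC, did so under each of the other scalings. Below 100 CPM, miR-133b and miR-184 fell in IVSC and rose in SVSC. A further 3, miR-136, miR-376b and miR-376c, fell in IVSC and had ratios above 2 in SVSC without a call, since they stood below 10 CPM in both SVSC libraries, and the ratio of miR-376b was 2.53 (0.589 to 8.55). These 5 were chosen after their values were seen. A 2-fold ratio in IVSC beside a ratio near 1 in SVSC was seen for 3 miRNAs, miR-1285, miR-195 and miR-214, and the converse for 19, among them miR-133a, miR-100, miR-103 and let-7a. The log2 change of miR-10b was larger in SVSC by 2.51 (2.48 to 2.53) and that of miR-339 by 3.28 (3.15 to 3.42). That of miR-146b was 1.69 in SVSC and 2.97 in IVSC. These differences between cultures have counting intervals and no test, since the interaction leaves no residual degrees of freedom.

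**Figure D2:**
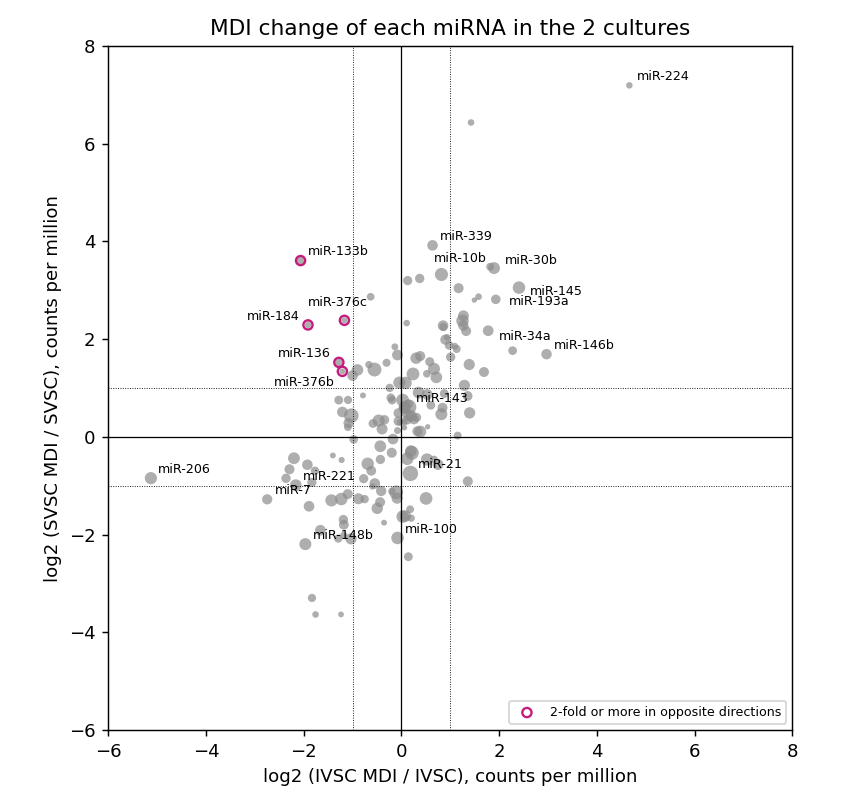
Log2 ratio of MDI over undifferentiated in SVSC (vertical) against IVSC (horizontal) for 155 miRNAs, 1 library per group; larger points are more abundant miRNAs, dotted lines mark 2-fold and rings mark 5 miRNAs with ratios past 2-fold in opposite directions, of which miR-133b and miR-184 were called in both cultures. miR-30b, miR-145 and miR-193a lie high in both cultures and miR-148b low in both, under all 5 scalings, and miR-206 lies far to the left.

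The additive fit asked which MDI effects were shared by both cultures. miR-206 fell by 4.00 on the log2 scale (SE 0.81, adjusted p = 0.000314 by edgeR). This effect rests on IVSC, since in SVSC its ratio was 0.558 (0.146 to 1.52) on 50 and 4 reads. The fit took its spread from all miRNAs together, so this p-value hardly weighs the gap between cultures for miR-206. miR-145 rose by 2.56 (SE 0.57, adjusted p = 0.00126), miR-30b by 2.51 (SE 0.59, adjusted p = 0.00155), and miR-224, reported to inhibit adipogenesis, by 5.34 (SE 1.26, adjusted p = 0.00155). miR-148b fell by 2.25 (SE 0.57, adjusted p = 0.00466). The other 4 were past 2-fold in the same direction in both cultures, miR-224 on 1 and 21 reads in SVSC. In all, 19 of 179 miRNAs passed the edgeR threshold, 11 up and 8 down, and 47 had an unadjusted p under 0.05. miR-7 (fell by 2.18, adjusted p = 0.0216) and miR-130b (fell by 1.95, adjusted p = 0.0237) followed, then miR-10b (1.90), miR-146b (2.17) and miR-193a (2.20), each with adjusted p = 0.0261. Adjusted over the list alone, 3 of 5 miR-30 members passed, as they did over all miRNAs tested. Of 20 miRNAs reported to promote adipogenesis 6 passed when adjusted over the list alone (5 over all), and among those reported to inhibit it 4 of 17 (4 over all). In the miR-17-92 clusters miR-20a and miR-363 passed both ways, and in the X-linked cluster miR-503 and miR-542 passed only when adjusted over the list alone (0 over all by edgeR), miR-542 being short of 2-fold on mature reads in both cultures. In the DLK1-DIO3 list 0 of 15 passed with edgeR either way. The count rests on the model: DESeq2 called 59 miRNAs (29 up, 30 down), and edgeR without the block called 0, with 38 at an unadjusted p under 0.05. With 1 library left out and no block, edgeR called 0 without IVSC, 9 without IVSC MDI, 0 without SVSC and 2 without SVSC MDI.

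Between the undifferentiated cultures, the question was how cells from muscle and from fat differed at the start. The skeletal muscle miRNA miR-206 was 1748-fold lower in SVSC than in IVSC (1326 to 2356), with 50 against 64588 reads. Of 11 detected miRNAs of the imprinted DLK1-DIO3 locus, 10 were lower in SVSC, among them miR-411 (15.1-fold; 13.8 to 16.6), miR-127 (14.5-fold; 13.6 to 15.6), miR-381 (11.4-fold; 11.03 to 11.7) and miR-299 (6.32-fold; 5.75 to 6.96). miR-129 was 11.6-fold higher in SVSC (11.01 to 12.2), with a log2 ratio of 1.68 on mature reads alone, and let-7a, which restrains proliferation, 2.83-fold higher (2.82 to 2.84). Of 148 miRNAs, 11 were higher and 31 lower in SVSC, 1 and 16 of them by at least 4-fold. Also higher were miR-100 (3.30-fold), miR-103 (2.60-fold), miR-27b, a repressor of PPARγ (2.58-fold), and miR-30d (2.03-fold). Also lower were miR-19b (5.47-fold; 5.24 to 5.71), miR-339 (3.75-fold), miR-32 (3.31-fold), miR-30a (3.18-fold; 3.13 to 3.24) and miR-708 (3.06-fold). Of the 42 calls 29 were made on mature reads as well, and among named miRNAs and list members those of miR-381 (11 and 0 reads), miR-221, miR-107, miR-30d, miR-122, miR-133a, miR-142, miR-376b, miR-376c and miR-494 were not. Scaling to the total of mature reads lowers every log2 ratio here. miR-30d, with 96.9% of its reads on the mature miRNA over the 4 libraries, lost its call mostly through that.

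The DLK1-DIO3 list had a median of -3.63 in SVSC over IVSC, below every one of 10000 random lists, and negative under all 5 scalings. The skeletal muscle list had 3 of 5 members lower (miR-206, miR-133b at 51.4-fold with 34.3 to 80.7, and miR-133a at 3.61-fold) and a median of -1.85 (percentile 4.55), while miR-1 had a ratio of 1.46 (1.44 to 1.49). In IVSC, 1247 of the 16453 miR-1 reads matched the mature miRNA exactly, and 16376 lay on it. Over the 4 libraries together 8.2% of miR-1 reads matched exactly. The same miR-133a and miR-133b were the members lower in the brown fat list, of 5 (median -0.70). let-7a was the member past 2-fold in the let-7 family, of 7, whose median was 0.64 (percentile 96.6). The miR-181 family had no member of 4 past 2-fold (median 0.47, percentile 95.4), though miR-181a passed it under TMM, DESeq2 scaling and without the most abundant miRNA. Among miRNAs reported to promote adipogenesis 4 of 19 were higher (miR-103, miR-107, miR-30d and miR-210) and 4 lower (miR-30a, miR-148a at 2.69-fold, miR-146b at 2.66-fold and miR-92a), with a median of -0.44. Among those reported to inhibit it, let-7a and miR-27b were higher and miR-221 and miR-369 lower, of 17, and the median of -0.16 was positive under the other 4 scalings.

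In the miR-30 family miR-30d was higher and miR-30a lower, of 5 (median -0.44, negative under all 5 scalings). In the miR-17-92 clusters miR-19b and miR-92a were lower, of 9, and the median of -0.31 turned positive under TMM, DESeq2 scaling and without the most abundant miRNA. miR-503 was lower (2.55-fold) in the miR-15 and miR-16 family of 7 (median -0.65) and in the X-linked cluster of 6 (median -0.64), short of 2-fold under DESeq2 scaling. Single members differed in the miR-29 (miR-29c lower, of 3; median 0.25), miR-23, miR-27 and miR-24 (miR-27b higher, of 5; median 0.16), miR-99 and miR-125 (miR-100 higher, of 5; median 0.09) and HOX lists (miR-10b lower, of 3; median -0.60). miR-221 was 2.17-fold lower (short of 2-fold under the other 4 scalings) and miR-222 had a ratio of 0.622. miR-34a and miR-34c had ratios of 1.28 and 1.95, that of miR-34c passing 2-fold under the other 4 scalings. No perivascular miRNA of 5 passed 2-fold (median -0.45). The endothelial miR-126 was 2.55-fold lower in SVSC (2.35 to 2.76; short of 2-fold under DESeq2 scaling), the blood cell miRNA miR-142 5.25-fold lower (4.19 to 6.63), miR-122 was 2.30-fold higher, and miR-9 had a ratio of 1.75. The log2 ratios moved by 0.35 with TMM (24 higher and 28 lower), 0.37 with DESeq2 size factors (28 and 24), 0.18 with all reads and 0.33 without the most abundant miRNA (24 and 30). miR-92a lost its call under TMM, DESeq2 scaling and without the most abundant miRNA, and miR-10b under DESeq2 scaling. Under all 5 scalings the 11 higher and 24 of the lower miRNAs were called, all 16 named first among them.

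After MDI, the question was whether the 2 cultures still differed. miR-206 was 89.8-fold lower in SVSC than in IVSC (35.0 to 330), with 4 against 2068 reads. miR-146b, which promotes adipocyte differentiation, was 6.44-fold lower (5.72 to 7.29), and miR-196b, of a HOX cluster, 9.15-fold lower (6.67 to 12.9). Of 11 DLK1-DIO3 miRNAs 6 were lower, among them miR-127 (5.69-fold; 4.62 to 7.08) and miR-381 (3.35-fold; 3.06 to 3.67). miR-218 was 6.67-fold higher in SVSC (5.70 to 7.81) and miR-129 5.17-fold higher (4.81 to 5.55), although its log2 ratio on the reads of the mature miRNA alone was -0.43. Of 147 miRNAs, 26 were higher and 15 lower, 5 and 7 of them by at least 4-fold. Also higher were miR-128 (4.50-fold; 4.02 to 5.03), miR-28 (3.51-fold) and miR-296 (2.95-fold), then miR-1271 (2.83-fold), miR-423 (2.68-fold), miR-339 (2.59-fold), let-7e (2.57-fold) and miR-744 (2.40-fold), of which the last 5 were short of 2-fold under scaling to all reads. That total counts some reads more than once. With these taken once it would move the log2 ratios by -0.29, and all of the 5 but miR-744 would stay past 2-fold. On the reads of the mature miRNA alone miR-296 had a log2 ratio of 0.75, and on exactly matching reads miR-339 had one of 0.47. Also lower were miR-708 (3.62-fold; 3.21 to 4.09), miR-34c (2.46-fold) and miR-20a (2.18-fold). Of the 41 calls 29 were made on mature reads as well. Among named miRNAs and list members those of miR-129, miR-296, miR-1271, miR-133a, miR-376a and miR-381 were not, nor those of miR-218 and miR-28, which had 0 mature reads in both libraries.

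The DLK1-DIO3 median after MDI was -1.76, again below every one of 10000 random lists and negative under all 5 scalings. Of the skeletal muscle list, miR-206 was lower and miR-133a higher (2.32-fold), of 5 (median -0.34), and miR-133b had a ratio of 0.991 (0.696 to 1.38). miR-133a was also the member higher in the brown fat list of 5, whose median of 0.19 was negative under scaling to all reads. In the list reported to promote adipogenesis miR-30b was higher and miR-146b and miR-20a lower, of 19, with a median of -0.34 (percentile 0.68). Among those reported to inhibit it, let-7c (2.35-fold), let-7e and miR-27b were higher and miR-224 and miR-369 lower, of 17, and the median of 0.03 was negative under the other 4 scalings. let-7c and let-7e were the members higher in the let-7 family of 7, whose median of 0.18 was negative under scaling to all reads. miR-30b was higher in the miR-30 family of 5 (2.09-fold, median -0.38) and miR-20a lower in the miR-17-92 clusters of 9 (median -0.20). No member passed 2-fold in the miR-29 (3 members, median -0.61) or miR-15 and miR-16 (7 members, median 0.65) families. Under scaling to all reads miR-29b and miR-29c were past 2-fold lower.

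The X-linked cluster had no member of 6 past 2-fold after MDI, and its median of 0.15 was negative under scaling to all reads and without the most abundant miRNA. The miR-23, miR-27 and miR-24 (miR-27b higher, of 5; median 0.43) and miR-181 lists (none of 4; median 0.24) turned negative under scaling to all reads as well. In the miR-99 and miR-125 list miR-99b was higher, of 5 (2.27-fold; median 0.59), and in the HOX list miR-10b was higher (2.21-fold) and miR-196b lower, of 3 (median -0.20). Of 5 perivascular miRNAs miR-214 was higher (2.20-fold), and the median of 0.41 was negative under scaling to all reads. miR-34a, miR-221 and miR-222 had ratios of 1.69, 1.04 and 1.01. miR-126 and miR-142 had ratios of 0.711 and 0.751, and miR-9 was 2.79-fold higher. The log2 ratios moved by -0.12 with TMM (21 higher and 20 lower), by -0.52 with all reads (7 and 29) and by -0.15 without the most abundant miRNA (19 and 25). miR-27b lost its call under the other 4 scalings, miR-30b under all but DESeq2 scaling, miR-10b and miR-214 with all reads and without the most abundant miRNA, and let-7c, miR-133a, miR-9 and miR-99b with all reads. miR-376a was then 7.18-fold lower but below 10 CPM of all reads. Under all 5 scalings, with the total of all reads as deposited, 7 of the higher and 13 of the lower miRNAs were called.

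**Figure D3:**
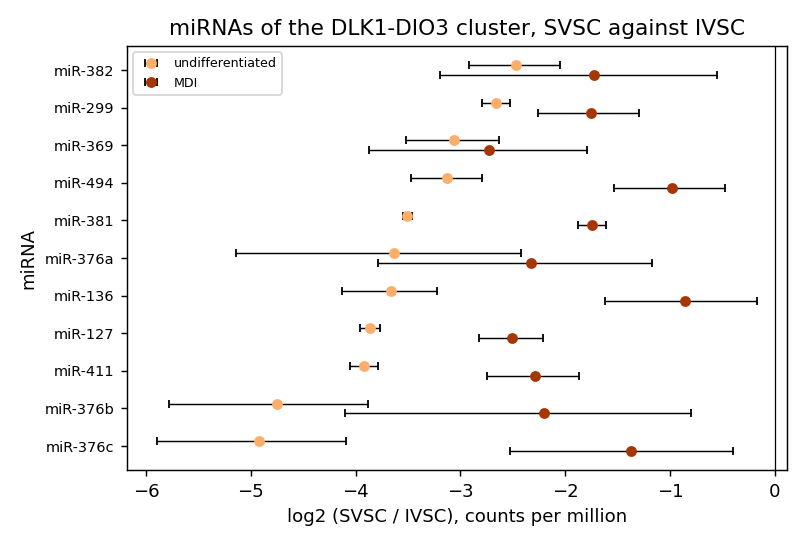
Log2 ratio of SVSC over IVSC for 11 miRNAs of the DLK1-DIO3 locus, undifferentiated and after MDI, 1 library per group; bars are exact 95% counting intervals. All points lie below 0, with medians of -3.63 undifferentiated and -1.76 after MDI, and both medians were negative under all 5 scalings.

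The differences between cultures before and after MDI share no library. Across 155 miRNAs they had a Pearson r of 0.513 and a Spearman rho of 0.192, and 53.6% had the same sign. Without miR-206 the Pearson r was 0.366. In both states 2 miRNAs were at least 2-fold higher in SVSC and 13 at least 2-fold lower. The additive fit, which averages over both states, called 5 miRNAs with edgeR, in the same direction in both states on all hairpin reads. In it the 2 states of a culture serve as replicates, so its p-values do not measure spread between animals or preparations. miR-206 was lower in SVSC by a log2 ratio of -9.24 (SE 0.89, adjusted p = 7.75e-18), miR-127 by -3.03 (SE 0.67, adjusted p = 0.000613), miR-381 by -2.47 (SE 0.59, adjusted p = 0.00219) and miR-411 by -2.96 (SE 0.72, adjusted p = 0.00227). Of the reads of miR-381 and miR-411, 99.95% and 93.0% lay on the rest of the hairpin. On mature reads miR-381 was not called between cultures in either state. miR-411 had 363, 137, 36 and 3 mature reads in IVSC, IVSC MDI, SVSC and SVSC MDI. miR-129 was higher by 3.11 (SE 0.62, adjusted p = 9.55e-05), while on the reads of the mature miRNA alone its log2 ratios were 1.68 undifferentiated and -0.43 after MDI. The next were miR-146b (-1.89, adjusted p = 0.145), miR-376b, miR-299, miR-369 and miR-376c, which did not pass. Of 15 DLK1-DIO3 miRNAs, 3 passed over all miRNAs tested and 9 adjusted over the list alone, all lower in SVSC. Of 24 miRNAs at an unadjusted p under 0.05 the edgeR fit thus called 5. DESeq2 called 26 (12 higher, 14 lower), and edgeR called 0 without the block, with 10 at an unadjusted p under 0.05. It also called 0 when IVSC, IVSC MDI, SVSC or SVSC MDI was left out, with 2, 5, 15 and 19 at an unadjusted p under 0.05.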

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

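The tests of explanations in this part were all chosen only after the results they address were seen.

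miR-206 was far higher in IVSC than in SVSC. Reads of the related miR-1 counted as miR-206 are argued against, since 95.4% of the miR-206 reads in IVSC matched mature miR-206 exactly. Mature muscle fibres, which hold abundant miR-1, are argued against as the source of most miR-206 reads, since IVSC had 0.255 miR-1 reads per miR-206 read. This ratio cannot exclude some fibres beside other cells that hold miR-206. Cells at an early myogenic stage are left open, since miR-133b, encoded beside miR-206, was 51.4-fold higher in IVSC undifferentiated (34.3 to 80.7), but after MDI its ratio of SVSC over IVSC was 0.991 (0.696 to 1.38) while miR-206 was still 89.8-fold lower in SVSC. Whether the vascular stem cells from muscle or other cells of that tissue hold miR-206 was not tested, and a difference between animals stays open.

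The DLK1-DIO3 miRNAs were higher in IVSC in both states. Scaling is argued against, since the highest median log2 ratio of SVSC over IVSC over 5 scalings and both states was -1.76. The C/D box RNA SNORD113, encoded in the same locus, was higher in IVSC too, by 11.8-fold before and 3.68-fold after MDI, as a higher output of the whole locus would give. With MDI it did not follow the miRNAs. In IVSC it went from 31.5 to 59.1 CPM of all reads, while 8 of 11 detected miRNAs of the locus fell on all hairpin reads. In SVSC it went from 2.7 to 16.1. A higher output of the whole locus is thus left open. A population of cells that alone held both miR-206 and the cluster and was lost with MDI is argued against, since the largest fall of a cluster miRNA in IVSC was 4.89-fold and the median fall 2.33-fold, against 34.9-fold for miR-206. Whether the cultures came from the same animal is not given, so tissue of origin and animal cannot be told apart, and both stay open.

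With MDI, more miRNAs changed in SVSC (82) than in IVSC (61), and more rose than fell. Lower depth of the SVSC MDI library and scaling are argued against for the number changed, since thinning the IVSC MDI library to that depth gave at most 65 over 100 draws, and SVSC had at least 19 more changes than IVSC under each of the 5 scalings. The excess of rises depends on the scaling, with a share of rises among the changes of 61.0% at first and 42.9% to 47.5% under TMM, DESeq2 and all-read scaling. Whether a few miRNAs that take most of the reads cause it is left open, since the share was 74.7% without miR-143 and 49.4% without miR-21, and each removal shifts every ratio by 1 factor. A difference in the response of the cultures or in the day of harvest stays open for the number changed, with 1 library per group. The make-up or quality of the SVSC MDI library stays open too, since thinning matched only the number of reads. With shared reads taken once, Ensembl non-coding RNAs held 26.4% of its reads, against 10.2% to 14.3% in the others.

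A group of 5 miRNAs stood out because their MDI log2 ratios passed 2-fold in opposite directions in the 2 cultures, and this difference was not tested. Of these, miR-136, miR-376b and miR-376c were below 10 CPM in both SVSC libraries and not called there, and the interval of miR-376b in SVSC included 1 (0.589 to 8.55). The log2 ratio in SVSC minus that in IVSC was 5.67 for miR-133b (4.92 to 6.42), 4.204 for miR-184 (3.57 to 4.84), 3.55 for miR-376c (2.27 to 4.83), 2.80 for miR-136 (2.00 to 3.61) and 2.55 for miR-376b (0.86 to 4.23). In SVSC these rest on few reads: 11 and 4 for miR-376b, 12 and 9 for miR-376c, 46 and 19 for miR-136, 24 and 42 for miR-133b, and 74 and 52 for miR-184, before and after MDI.

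Signals outside the miRNA comparisons stood out in the other RNA classes. Y RNA took a 5.998-fold larger share of all reads with MDI in IVSC (894 to 5151 reads) and a 6.70-fold larger share in SVSC (751 to 1010 reads). SNORD52 was at 0.472 times its undifferentiated share in IVSC (1914 to 868 reads) and at 0.0919 times in SVSC (3902 to 72 reads). SNORD113 rested on 681 reads in IVSC against 69 in SVSC undifferentiated, and on 1225 against 83 after MDI. The Ensembl transcripts ENSSSCT00000020550 and ENSSSCT00000020202, which hold nearly the same reads and whose identity is not given in the sources used here, each took 18.3% of all reads in SVSC MDI, against 7.24%, 4.90% and 5.92% in IVSC, IVSC MDI and SVSC. ENSSSCT00000021748 was at 0.441 and 0.320 times its undifferentiated share with MDI in IVSC and SVSC, and ENSSSCT00000021182 at 4.41 and 3.73 times.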

How the results depend on the processing

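Mature reads, summed hairpin copies and thinned libraries were chosen as alternatives only after the results were seen. The restriction to pig entries was not run, since the comparisons used only pig hairpins throughout (Rfam families also hold miRNA reads and were not used). Of 148 alternative values of the main counts and correlations, 100 stayed within 1.5 times of the main value and 48 moved. Among log2 ratios of single miRNAs 211 stayed, 367 moved beyond their counting interval and 7 changed sign. Of 64 list medians 18 differed in sign under at least 1 other scaling. Where a threshold or filter was raised or lowered, the count changed by construction. Another scaling moves every log2 ratio of a comparison by 1 factor, so its counts moved by construction too. Exact and mature reads combine such a factor, from their own total, with the change of read class, and how much each added was not tested. For all others below the cause was not tested. Depth limits SVSC MDI most, where 3 reads are 1.17 CPM.

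For MDI in IVSC, 40 rose at 1.5-fold and 4 at 4-fold, against 25. Falls, 36 at first, were 21 under scaling to all reads, 20 with a filter of 100 CPM, 7 at 4-fold, 19 on exact reads and 23 on mature reads. For MDI in SVSC, rises (50) were 33 under scaling to all reads and 23 at 4-fold, and falls (32) were 20 with a filter of 100 CPM and 9 at 4-fold. Between undifferentiated cultures, miRNAs higher in SVSC (11) were 24 with TMM, 28 with DESeq2 size factors, 24 without the most abundant miRNA, 6 with a filter of 100 CPM, 30 at 1.5-fold, 1 at 4-fold, 18 on exact and 7 on mature reads. Those lower (31) were 16 with a filter of 100 CPM, 61 at 1.5-fold and 16 at 4-fold. After MDI, those higher (26) were 7 under scaling to all reads, 43 at 1.5-fold, 5 at 4-fold and 9 on exact reads. Those lower (15) were 29 under scaling to all reads, 25 without the most abundant miRNA, 8 with a filter of 100 CPM, 28 at 1.5-fold and 7 at 4-fold.

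Ratios past 2-fold in opposite directions with MDI (5) were 0 with a filter of 100 CPM. Changes in IVSC alone (3) were 1 with that filter and 7 with TMM, and in SVSC alone (19) 12 with that filter and 10 on exact reads. In the additive fits, MDI calls (19 with edgeR, 47 at an unadjusted p under 0.05) were 59 with DESeq2, 0 without the block (38 unadjusted) and 0 to 9 with 1 library left out. Culture calls (5, with 24 unadjusted) were 26 with DESeq2, 0 without the block (10 unadjusted) and 0 to 0 with 1 library left out (2 to 19 unadjusted). In these last fits a lone library is assumed to vary like the others.

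The log2 ratios of single miRNAs that changed sign did so with the read class, and the reads of each class were scaled to their own total. For MDI in SVSC that total raises every log2 ratio on mature reads and lowers every one on exact reads. With MDI in IVSC miR-299 was at 1.51 on 3 and 9 exact reads and miR-381 at 0.26 on 11 and 14 mature reads. With MDI in SVSC miR-140 was at 0.28 on mature reads, while its 0.82 on exact reads is only an upper bound, from 9 and 0 reads, and miR-20a at 0.46 on exact reads. Between cultures after MDI miR-129 was at -1.05 on exact and -0.43 on mature reads.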

Other observations

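The values here were chosen only after they were seen, and no explanation was tested. miR-224, reported to inhibit adipogenesis, was close to absent before induction and present after it. It went from 12 to 340 reads in IVSC (25.4-fold higher; 14.3 to 49.6) and from 1 to 21 reads in SVSC (146-fold higher; 23.5 to 6054). miR-4334 went from 17 to 51 reads in IVSC (2.68-fold higher, 1.52 to 4.96) and from 5 to 62 reads in SVSC (86.4-fold higher, 35.1 to 276). All of these reads lay on the rest of its hairpin, with 0 on the mature miRNA. The HOX cluster miRNA miR-196b was at 126 and 139 CPM in IVSC before and after MDI, and at 82.8 and 15.2 CPM in SVSC. miR-10b, of another HOX cluster, was at 3980 and 7023 CPM in IVSC, and at 1546 and 15493 CPM in SVSC.

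SNORD113 and the miRNAs of the same locus were compared with MDI in IVSC. SNORD113 had 681 reads before and 1225 after induction, while 8 of 11 detected DLK1-DIO3 miRNAs fell on all hairpin reads. Of these falls, those of miR-136, miR-299, miR-376b, miR-376c and miR-381 were not called on mature reads. In SVSC, SNORD113 had 69 reads before and 83 after induction, 2.7 and 16.1 as CPM of all reads. Rfam entries of the mir-154 family, scaled as CPM of all reads, stood at 126 before and 90.5 after induction in IVSC. In SVSC they stood at 17.8 and 24.6. miR-1 was read in all 4 libraries at 1242, 882, 1818 and 661 CPM in IVSC, IVSC MDI, SVSC and SVSC MDI, while miR-499, another miRNA of striated muscle, stood at 12.8, 13.3, 9.20 and 10.5 CPM.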
